A study of Mus musculus with 6 samples.

How the data were processed

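RNA of whole whisker pads from 3 wild-type and 3 Trps1 mutant mouse embryos at E12.5 was hybridised as biotin-labelled cRNA to 6 one-colour Affymetrix MOE430A arrays, per the labels. The deposited value table holds 1 intensity per probe set and array, 22690 probe sets in all, on a linear scale. The method that turned probe intensities into these signals, and its software, are not given in the sources used here. Every array has the same 2% trimmed mean of 250.1, as arrays scaled to a common target have, and the direction and scale of these values are therefore known while the summary method is not. The authors also deposited a table of 65 probe sets, with a linear ratio (fold) and 2 normalized log2 group values each. It was made with GeneSpring GX 10.0, per the submitters' design text, which states an unpaired test with an unadjusted p of at most 0.05 and a fold of at least 1.5. The fold in the authors' deposited table equals 2 to the power of the difference between its log2 columns, to within 2.7e-07, and its text column gives the direction of wild-type relative to mutant. How the authors normalized or averaged arrays for that table is not given in the sources used here.

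Groups and replicate numbers came from the sample titles. No pair of arrays shared equal signals at more than 0.358% of probe sets, so no array was counted as a repeat of another. Whether the numbers pair arrays across groups was left unsettled by the values. The rule asks that deviations from the group mean correlate above 0.1 for every pair with the same number, and the probe sets to use were not fixed. The correlations were 0.038, 0.069 and 0.14 over all probe sets, and 0.14, 0.28 and 0.33 over the 6551 with a mean log2 signal above 8. The labels do not state what a shared number stands for. The fit without a block, as designed, stayed the main one, and the value with the replicate number as a block is printed beside each list call it ended.

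The 64 control probe sets were left out, which left 22626. Signals were used as deposited, with 16 added before taking log2, since the values are linear with many near 0. The offset pulls the differences of dim genes toward 0. Gene names came from the platform annotation, updated by gene number to a mouse reference annotation (assembly GRCm38.p6) that was used for names and for the order of genes only. Of the probe sets tested, 20380 had 1 gene, 691 had several and 1555 were not in the annotation table, and 20351 were matched to the reference by gene number. Genes were represented by the probe set with the highest mean over the 6 arrays, which gave 12393 genes, and probe sets with several genes or none were left out of the gene table.

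Mutant was compared with wild-type by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over all probe sets or all genes and an adjusted p under 0.05 as the threshold. The study's threshold was counted beside it, with limma and with the methods' unpaired test of equal variance. Gene lists of at least 5 measured genes, 29 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the lists. Beside each list stand the members that passed over all genes and those that passed when adjusted over the list alone. The standard error of a list is that of its mean over arrays. The programs were tested on simulated arrays with the real means and spreads, where 100 probe sets each were changed by a log2 fold of 1 and of 2. In that test 6 unchanged probe sets were called, 0 were called with no change simulated, and the 1 list that was shifted, by -0.5, was the 1 called. Noise was drawn independently for each probe set, so the test does not cover smaller shifts of a list or correlated genes.

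Genes named in the text were chosen by a rule written before the data were examined. It takes Trps1, up to 12 genes per direction by fold among those that pass, or, as here, filled by smallest unadjusted p among genes of at least 1.5-fold whose groups do not overlap. It also takes up to 4 members of each list by smallest unadjusted p, and up to 10 genes at the head of the authors' deposited table. List members with an unadjusted p of 0.05 or more were named only where they were needed to describe a list. Apcdd1, Dcn, Kera, Nefl, H2-K1, Hba-x, Hbb-bh1, Hbb-y, Cldn10, Dennd1a, Ccn3, 3110070M22Rik and Lef1 fall outside the rule and were named after their values were seen, as were probe sets named for disagreeing with others of their gene and those shared by several globin or H2 genes.

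Alternatives set before the data were examined were quantile normalization, a shift to equal medians, removal of the 7542 probe sets lowest in mean signal, a trended or robust variance prior, array weights, the replicate number as a block, an offset of 1 or a floor of 32 in place of 16, removal of probe sets marked as sharing sequence, the methods' test, an adjusted p under 0.1, leaving out each array, averaging a gene's probe sets, the estimated correlation and fry. Leaving out both replicate 3 arrays, keeping probe sets above the highest bacterial control (33.8), and taking the genes of the authors' deposited table out of the lists were chosen after seeing the data, and the last takes out genes picked for differing on these arrays, so that smaller means are expected from it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.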

Results

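Gene expression was measured in the whisker pad, the facial skin in which the vibrissa follicles form, of mouse embryos at E12.5, mid-gestation. At this stage epithelial thickenings called placodes, with condensing dermis beneath them, mark the future follicles. The series holds 6 Affymetrix MOE430A arrays of total RNA, 3 from wild-type and 3 from Trps1 mutant embryos. The study's design text states that each array came from a separate embryo, so the spread within a group is a spread between embryos. Trps1 encodes an atypical GATA-type zinc finger protein that represses transcription, and the series title gives its transcriptional targets in vibrissae as the question. All differences below are mutant minus wild-type on a log2(signal + 16) scale, signals are means ± SD with n = 3 per group, and p-values are two-sided and come from limma unless another test is named.

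The 6 arrays had been brought to one level before deposit, each with a 2% trimmed mean signal of 250.1 and medians of 90.5 to 101.5. Bacterial control probe sets, of which there were 27, read 0.4 to 33.8, and 27 to 29.3% of the mouse probe sets on each array lay at or below 33.8. The ratio of the 3' to the 5' actin control probe set was 1.07 to 1.19 on 5 arrays and 1.35 on mutant replicate 3. Xist, the RNA made from the inactive X chromosome of females, read 461.5 on wild-type replicate 3 and 44 to 93.7 on the other 5 arrays. The Y-linked gene Eif2s3y read 11.9 on that array and 207 to 272 on the other 5. By these values wild-type replicate 3 read as female and the other 5 arrays as male, while the labels give no sex. Sex was thus not balanced between the groups. The first principal component held 28.7% of the variance and set both replicate 3 arrays (36.8 in wild-type, 31 in mutant) apart from the other 4 (-4.89, -5.8, -30.8 and -26.3). Differences at which 1 group lies near the bacterial controls are limited by that background, and the number of arrays limits the precision of every value. A gene is said to read under the highest bacterial control where both of its group means do. Differences with only 1 group mean under it are given without that remark. Among them are those of Nog, Fgf10, Foxf1, Wnt5b, Myog, Elavl3, Hemgn, Tyms, Fosb, Hoxc9, Usp9y and Ly86. The same holds for Nobox, Tcam1, Olfr17, Galc, Klf15, Ankrd33 and Tmem143.

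The targeted gene was examined first. Trps1, measured by 1 probe set, read 807.6, 1061.4 and 748.1 in the wild-type embryos and 1297.3, 1491.9 and 1506.7 in the mutant embryos, all 3 above every wild-type value. The log2 difference was 0.72 (SE 0.18), with a limma adjusted p = 0.598 over all genes. An exact permutation test of the 6 values gave p = 0.1, the smallest p that 3 arrays against 3 can give. The labels do not state which part of the gene the mutation alters or where this probe set lies relative to it, so the level does not check the labels.

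The comparison of mutant with wild-type whisker pads asked which genes depend on Trps1 while the vibrissa placodes form. Among 29 gene lists fixed before the data were examined, markers of placode and follicle epithelium and markers of red blood cells fell on average in the mutant and markers of neurons rose, by camera with a preset correlation between genes. The placode list fell by a mean of 0.24 on the log2 scale over 22 genes, the erythroid list by 0.16 over 20 genes, and the neuron list rose by 0.15 over 35 genes. With an estimated correlation 0 of the 3 passed (adjusted p = 0.521 for placode, 0.671 for erythroid and 0.521 for neuron markers). The estimates were -0.0054, 0.086 and -0.012 in that order. For placode and neuron markers they lay below the preset 0.01, so a higher correlation between genes was not what ended those calls. With the replicate number as a block 0 passed. Over all genes 0 single genes passed limma with Benjamini-Hochberg adjustment, and 664 had an unadjusted p under 0.05. The genes with the clearest separation between groups included Epyc, a small leucine-rich proteoglycan of cartilage, at 35.8 ± 12.3 in wild-type and 197.7 ± 32 in mutant pads, and Prdm1, a transcriptional repressor present in dermal condensates, at 295.3 ± 12.2 and 128.3 ± 9.56.

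Placode and follicle epithelium genes had a mean difference of -0.24 (SE 0.09 over arrays) and a median of -0.06, with 15 of 22 members lower and an adjusted p = 0.0455 by camera with the preset correlation. With an estimated correlation the adjusted p = 0.521, and with the replicate number as a block it was 0.121. Adjusted over the list alone, 3 members fell and 0 rose, against 0 over all genes tested. Lhx2, a LIM homeodomain factor of hair follicle progenitors, read 91.5 ± 26.9 in wild-type and 31.6 ± 11.5 in mutant pads, a difference of -1.18. The HMG-box factor Sox21 read 80.2 ± 28.6 and 21.6 ± 13.2, a difference of -1.36. For Dkk4, a secreted Wnt inhibitor of placodes, the values were 110.8 ± 25.1 and 53.9 ± 6.60, a difference of -0.84. These 3 genes are also in the table of genes the authors deposited from the same arrays, so their direction here is not independent evidence. Edar, the ectodysplasin receptor of placodes, read 24.9 ± 26.3 and 7.73 ± 0.751, with both group means under the highest bacterial control. The call held without wild-type replicate 3 (adjusted p = 0.00536) and was lost without each of the other 5 arrays (adjusted p of 0.1 without mutant replicate 2, 0.121 without mutant replicate 1, 0.183 without wild-type replicate 2, 0.207 without wild-type replicate 1 and 0.282 without mutant replicate 3). With the genes of the authors' table taken out, an alternative chosen after seeing the data, the mean was -0.10 (adjusted p = 0.628), and without both replicate 3 arrays, also chosen after seeing the data, it was -0.31 (adjusted p = 0.0923).

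**Figure D1:**
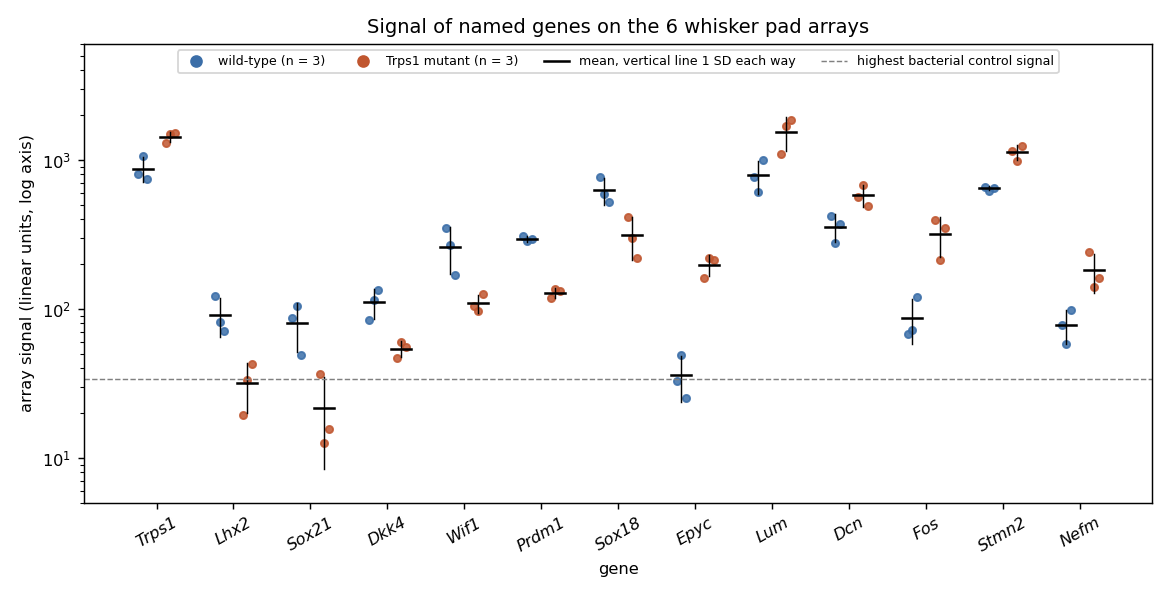
Array signal in linear units on a log axis for 13 genes, with each dot 1 embryo, 3 per group, the horizontal bar the group mean and the vertical line 1 SD each way; the dashed line is the highest bacterial control signal (33.8). Mutant dots lay below every wild-type dot for Lhx2, Sox21, Dkk4, Wif1, Prdm1 and Sox18 and above every wild-type dot for Trps1, Epyc, Lum, Dcn, Fos, Stmn2 and Nefm.

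Secreted Wnt inhibitors, 16 of them measured, had a mean difference of -0.07 and a median of 0.04, which differ in sign, and did not pass (adjusted p = 0.571). Adjusted over the list alone, 2 members fell, Dkk4 and Wif1, both of them in the authors' deposited table. Wif1, which binds Wnt proteins outside the cell, read 261.1 ± 90.9 in wild-type and 108.8 ± 14.7 in mutant pads, a difference of -1.10 (SE 0.26, adjusted p = 0.59 over all genes). Sostdc1, an inhibitor of Wnt and BMP signalling, differed by -0.79 at its brightest probe set (-0.43 without wild-type replicate 1). At its other probe set the difference was -0.27 (SE 0.60) and the groups overlapped, so that value carries no clear direction. Igfbp4 differed by -0.46 at its brightest probe set and by -0.63 to -0.04 at its others, while Frzb differed by 0.76. At a dimmer probe set of Frzb the difference was 0.32 (SE 0.41) and the groups overlapped, so that value carries no clear direction. Apcdd1, a membrane-bound Wnt inhibitor named after its values were seen, differed by -0.29 at its brightest probe set (-0.12 without wild-type replicate 1) and by -0.50, -0.66 and -0.73 at its other 3. Wnt/beta-catenin response genes had a mean of -0.06 over 17 genes (adjusted p = 0.7), with the same 2 members below the list's own threshold and with values in both directions, as in Sp5 at 1.08 (0.71 without wild-type replicate 3) and Nkd2 at -0.66. Wnt ligands and receptors averaged 0.0042 over 37 genes (adjusted p = 0.824), where Wnt5b differed by 0.39 and Lgr6 by 0.39. The 1 member of that list below the list's own threshold was Wnt9a, at 17.0 ± 2.15 in wild-type and 3.10 ± 1.25 in mutant pads, both under the highest bacterial control.

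Other signalling lists did not pass, and 0 of their members passed over the list alone. BMP and TGF-beta pathway genes averaged -0.03 over 34 genes (adjusted p = 0.824). Within them the BMP antagonist Nog differed by -0.99, the receptor Bmpr2 by 0.44 and Bmp4 by 0.45 (0.29 without wild-type replicate 3), while the receptor Bmpr1b read 28.4 ± 7.97 in wild-type and 8.0 ± 4.99 in mutant pads, under the highest bacterial control. Hedgehog pathway genes averaged -0.07 over 15 genes (adjusted p = 0.538), with Foxf1 at 1.01. FGF pathway genes averaged -0.11 over 25 genes (adjusted p = 0.487), with Fgf10 at -0.95 (-0.58 without mutant replicate 3) and Fgfr2 at 0.38. Another bright probe set of Fgfr2 differed by 0.16 (SE 0.38), and there the groups overlapped. Eda/Edar and NF-kB pathway genes averaged 0.06 over 14 genes (adjusted p = 0.571), with Traf6 at 0.46 and at 0.15 at its 2 other probe sets.

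Dermal condensate and fibroblast markers averaged -0.08 over 29 genes, with 13 members higher and 16 lower (adjusted p = 0.654). Prdm1, at a difference of -1.11 (SE 0.14), fell when adjusted over the list alone (adjusted p = 0.293 over all genes). Sox18, a factor of endothelium and dermal papilla, read 626.4 ± 128.1 in wild-type and 312.3 ± 98.0 in mutant pads, a difference of -0.99. The cell cycle inhibitor Cdkn1a differed by -0.69 and the forkhead gene Foxd1 by -0.91, which was -0.46 without wild-type replicate 1. Lumican (Lum) read 788.5 ± 194.4 and 1544 ± 399.7, a difference of 0.95, and decorin (Dcn) 355.9 ± 74.8 and 578.7 ± 96.4, a difference of 0.69. Extracellular matrix and adhesion genes averaged 0.08 over 48 genes (adjusted p = 0.276), with 5 members higher and 0 lower at an unadjusted p under 0.05 and 0 past the threshold over the list alone. Besides Lum and Dcn these were tenascin C (Tnc) at 0.60, lysyl oxidase (Lox) at 0.57 and laminin alpha 2 (Lama2) at 0.85, the last at 0.55 without mutant replicate 3.

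Skeletal and muscle markers did not pass as lists. Cartilage markers averaged 0.05 over 26 genes (adjusted p = 0.734), and 1 member, Epyc, rose when adjusted over the list alone. The Epyc difference was 2.06 (SE 0.22, adjusted p = 0.161 over all genes), and it passed over all genes when the 7542 dimmest probe sets were left out (adjusted p = 0.0218). Bone markers averaged 0.17 over 14 genes (adjusted p = 0.276), with the endopeptidase Phex at 9.03 ± 8.60 in wild-type and 34.8 ± 11.5 in mutant pads. Skeletal muscle markers averaged -0.02 over 36 genes (adjusted p = 0.85), where Myog differed by 1.01 and Mylpf and Myom1 read at or below the highest bacterial control in both groups. Craniofacial mesenchyme transcription factors averaged -0.01 over 32 genes (adjusted p = 0.866), with Sox11 at 537.5 ± 128.3 and 1030 ± 155, a difference of 0.93, and Eya1 at 0.78. Epidermis and periderm markers averaged 0.08 over 37 genes (adjusted p = 0.538), with 24 members higher and 13 lower. In that list E-cadherin (Cdh1) differed by -0.44 (-0.15 without mutant replicate 1), and integrin beta 4 (Itgb4) read under the highest bacterial control in both groups. The epidermis list passed in 1 other setting, without wild-type replicate 1 (mean 0.19, adjusted p = 0.0202).

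Neuron markers had a mean difference of 0.15 (SE 0.03 over arrays) with 23 of 35 members higher and an adjusted p = 0.0373 by camera with the preset correlation. With an estimated correlation the adjusted p = 0.521, and fry, which tests whether a list's genes move one way on balance, gave an adjusted p = 0.0511. With the replicate number as a block the adjusted p = 0.072. Adjusted over the list alone 1 member rose, Stmn2, a growth cone protein, at 645.1 ± 20.5 in wild-type and 1123 ± 128.6 in mutant pads at its brightest probe set. Its other probe set read 566 ± 83.3 and 725.2 ± 99.4, a difference of 0.35 (limma adjusted p = 0.966 over all probe sets), and there the groups overlapped. The neurofilament genes Nefm and Nefl differed by 1.05 and 0.67 and the axonal adhesion gene Cntn2 by 0.68, while Elavl3 differed by -1.30 at its brightest probe set, and its 2 others read under the highest bacterial control in both groups. The 10 brightest neuron markers had a median difference of 0.17, and 9 of them were higher. The call held without wild-type replicate 1 (adjusted p = 0.0202) and was lost without wild-type replicate 2 (0.103), wild-type replicate 3 (0.173), mutant replicate 1 (0.0788), mutant replicate 2 (0.0629) and mutant replicate 3 (0.282). Without both replicate 3 arrays the mean was 0.12 (adjusted p = 0.563), and without the authors' table genes 0.13 (adjusted p = 0.126).

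Erythroid markers had a mean difference of -0.16 (SE 0.10 over arrays) with 12 of 20 members lower and an adjusted p = 0.0373 by camera with the preset correlation. With an estimated correlation the adjusted p = 0.671, and with the replicate number as a block it was 0.072. No member passed over the list alone. The anion exchanger Slc4a1 differed by -0.56, biliverdin reductase B (Blvrb) by -0.49 (-0.32 without wild-type replicate 1), Hemgn by -0.50 and the erythroid factor Gata1 by -0.40 (-0.24 without wild-type replicate 3). The embryonic globin genes Hba-x and Hbb-bh1 differed by -0.27 (-0.10 without mutant replicate 3) and -0.26 (-0.11 without wild-type replicate 3), and 7 embryonic globin probe sets averaged -0.23 (SE 0.10 over arrays), among them the brightest probe set of Hbb-y at 0.01. Of the bright probe sets shared by the adult genes Hba-a1 and Hba-a2, which are not in the gene table, 1 differed by -2.63 and the others by 0.07 and -0.03. The highest signal on an array was 14473.2 to 22362.9, and differences at globin probe sets are limited where they read near it. The call held without wild-type replicate 2 (adjusted p = 0.0464) and without mutant replicate 2 (0.00218), and was lost without wild-type replicate 1 (0.0703), wild-type replicate 3 (0.0612), mutant replicate 1 (0.263) and mutant replicate 3 (0.282). Without both replicate 3 arrays the mean was -0.09 (adjusted p = 0.45), and without the authors' table genes -0.14 (adjusted p = 0.126).

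Markers of other cell types that a whole whisker pad can hold did not pass. Olfactory and nasal epithelium markers averaged -0.15 over 16 genes (adjusted p = 0.276), and 2 members fell when adjusted over the list alone, Lhx2 and the Notch target Hes5, the latter at 41.8 ± 28.0 in wild-type and 7.67 ± 3.98 in mutant pads. Hes5 read 74, 27.7 and 23.6 in wild-type replicates 1 to 3, so only replicate 1 lay above the highest bacterial control. The other probe set of Hes5 read under that control in both groups. Insm1 of that list differed by -0.63 (-0.40 without mutant replicate 3), and Six6 read under the highest bacterial control in both groups. Schwann cell and melanoblast markers averaged -0.09 over 15 genes (adjusted p = 0.538), with the neurotrophin receptor Ngfr at -0.79 and Fabp7 at -0.54. Endothelial markers averaged -0.04 over 25 genes (adjusted p = 0.7), with Flt4 at -0.61 and Robo4 at -0.48 beside Sox18. Macrophage and leukocyte markers averaged -0.01 over 22 genes with a median of 0.06 (adjusted p = 0.773), and Ly86 differed by -0.89.

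Immediate early and heat shock genes averaged 0.12 with a median of -0.05 over 28 genes (adjusted p = 0.571). Fos, an early response transcription factor, rose when adjusted over the list alone, from 87.1 ± 29.3 in wild-type to 317.6 ± 94.7 in mutant pads, a difference of 1.69. Egr1 differed by 0.94, Klf6 by 0.49 (0.31 without wild-type replicate 2) and Fosb by 0.48. Cell cycle genes averaged -0.02 over 40 genes (adjusted p = 0.724), with Tyms at 0.35, and cell cycle inhibitors and apoptosis genes averaged -0.07 over 24 genes (adjusted p = 0.538), with Gadd45g at -0.68 beside Cdkn1a. GATA family genes and Trps1 partners averaged 0.02 over 15 genes (adjusted p = 0.85), in which Zfpm2, a cofactor of GATA proteins, differed by -0.62 at its brightest probe set. The other probe set of Zfpm2 read under the highest bacterial control in both groups. Zfpm2 lies 11 measured genes from Trps1, so a chromosome segment of another strain around Trps1 stays open for it. Hox genes averaged -0.03 over 31 genes (adjusted p = 0.7), with Hoxc9 at 0.81 and with Hoxd11, Hoxa4 and Hoxc8 at or below the highest bacterial control in both groups. Hypoxia and glycolysis genes averaged -0.09 over 24 genes (adjusted p = 0.276), with Ddit4 at -0.33. Ribosomal protein genes averaged 0.04 over 33 genes (adjusted p = 0.654), with Rpl7 at 0.21. Sex chromosome marker genes averaged 0.54 (SE 0.32) over 6 genes (adjusted p = 0.218), where Usp9y differed by 0.81 (0.53 without wild-type replicate 3), and wild-type replicate 3 was the array that stood apart. That array was the only one that read as female, so the mean of this list does not separate genotype from sex.

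**Figure D2:**
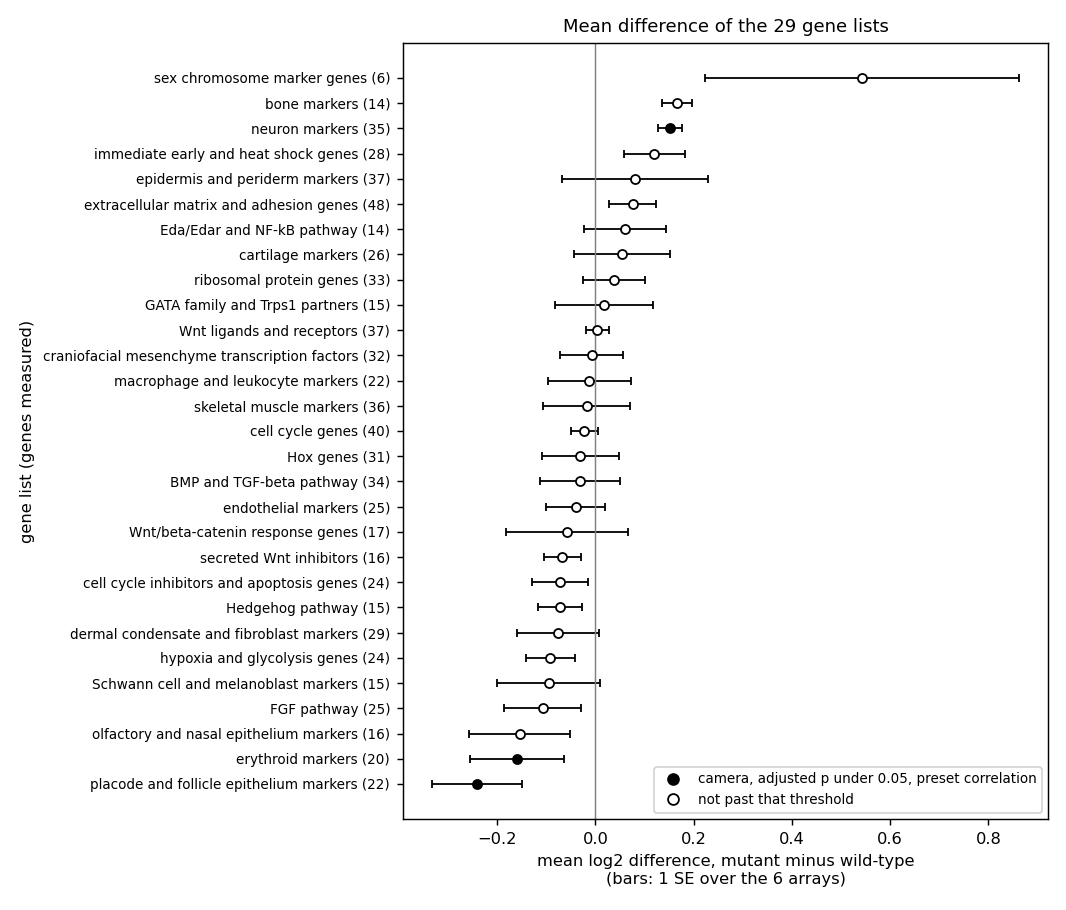
Mean log2 difference (mutant minus wild-type, horizontal axis) of each of the 29 gene lists, with the number of genes measured beside its name and bars of 1 SE over the 6 arrays; filled dots passed camera with the preset correlation. The 3 filled dots are neuron markers at 0.15, erythroid markers at -0.16 and placode and follicle epithelium markers at -0.24, and 0 lists passed with an estimated correlation.

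Genes outside the lists were taken by the fixed rule, as the genes of at least 1.5-fold and without overlap between groups that had the smallest unadjusted limma p. None of them passed over all genes, with adjusted p-values of 0.161 to 0.547. Myoglobin (Mb) read 12.9 ± 1.07 in wild-type and 58.3 ± 7.97 in mutant pads, a difference of 1.36. Iigp1, an interferon-inducible GTPase, read 98.8 ± 16.5 and 187.1 ± 4.87, a difference of 0.83. Higher readings were also found for the palmitoyltransferase Zdhhc12 (1.29), Nobox (1.26), Tcam1 (1.33) and Tmem267 (1.05), as well as the unnamed transcript 4833420G17Rik (0.92). The class I histocompatibility gene H2-D1 read 365.2 ± 55.0 and 138.2 ± 43.4, a difference of -1.34 at its brightest probe set, with -0.83 at the next brightest. Galactosylceramidase (Galc) differed by -1.50 at its brightest probe set, with its 2 others under the highest bacterial control in both groups, Klf15 by -1.19, the olfactory receptor Olfr17 by -1.45, the histone gene H2bc22 by -1.11, Ankrd33 by -1.09 and Tmem143 by -0.81. The remaining genes of the rule besides Wnt9a, which were Kcnd2, Klrb1a, Sez6l, Ang3 and Pdgfd, read at or below the highest bacterial control in both groups. Other probe sets of the same gene differed in sign from the brightest for Wnt5b, Phex, Tyms, Slc4a1, Hoxa4, Kcnd2, Elavl3, Galc and H2-D1, in each case only at probe sets that read under the highest bacterial control in both groups and so carry no direction, and for Ywhaz at bright ones that differed little (-0.04 and -0.05). For Hbb-y the brightest probe set, at 0.01, was opposed by bright ones at -0.17 and -0.27.

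Over all 22626 mouse probe sets, 0 passed an adjusted p under 0.05 by limma (smallest 0.131), and over 12393 genes 0 passed (smallest 0.161). At an unadjusted p under 0.05 there were 1193 probe sets, 656 higher and 537 lower, which is 5.27% where chance gives 5%. The 3 values of one group lay wholly beyond those of the other for 10.2% of probe sets, where chance gives 10%. The study's own threshold, an unadjusted p of at most 0.05 with at least a 1.5-fold difference, was met by 723 probe sets with limma (388 higher, 335 lower) and by 359 with the methods' unpaired test (193 higher, 166 lower), of which 0 held after Benjamini-Hochberg adjustment (smallest 0.491). It was met by 1121 without mutant replicate 3, by 1250 without both replicate 3 arrays, by 310 without the 7542 dimmest probe sets, by 311 with a floor of 32 and by 397 above the bacterial controls. In simulated data of the same design, limma called 18% of probe sets changed by a log2 fold of 1 and 70% of those changed by a log2 fold of 2.

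The authors' deposited table lists 65 probe sets, 42 higher and 23 lower in the mutant once its direction, which is given for wild-type, is turned. The folds in the authors' deposited table run from 1.50 to 7.05. In the signal values the direction was the same for 65 of 65, and the 2 log2 differences correlated across these probe sets with r = 0.966. These probe sets were picked for differing on the same arrays, so neither value is independent evidence. Of the 65, 61 had an unadjusted limma p of at most 0.05, 57 also met the 1.5-fold limit, 52 met the study's threshold with the methods' test, and 0 had an adjusted p under 0.05. At the head of the authors' deposited table, with a fold of 7.05, stands a probe set shared by the adult alpha globin genes Hba-a1 and Hba-a2, with a difference of -2.63 (SE 0.23) here. Among the named entries that follow are a probe set of Paip1 at a fold of 4.47 in the authors' deposited table (-2.29 here), Fos at 3.09, Epyc at 3.05 and a probe set of Ywhaz at 2.42 (1.36 here). The calcium-binding protein gene Calb1, at 2.27 in the authors' deposited table, read 53.6 ± 3.42 in wild-type and 109.5 ± 28.7 in mutant pads. The brightest probe sets of Paip1 and Ywhaz differed by -0.28 (-0.06 without mutant replicate 1) and 0.47 (-0.07 without wild-type replicate 3), less than the probe sets in the authors' deposited table.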

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

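Leaving out both replicate 3 arrays, keeping only signals above the bacterial controls and taking the authors' table genes out of the lists were chosen after seeing the data. Trps1 stayed higher in the mutant and not past the threshold under every alternative run (0.58 to 0.86, with adjusted p of 0.496 to 0.905). Counts of genes past an adjusted p under 0.05 were 0 in every setting but 1. Removing the 7542 dimmest probe sets gave 2 probe sets, of which 1 is Epyc and the other is shared by Hba-a1 and Hba-a2, and 1 gene, Epyc, with fewer tests to adjust for. A trended prior gave 1 probe set and so did keeping signals above the bacterial controls, in both the shared globin probe set. Leaving out mutant replicate 3 gave 1, a probe set of Rps9, and the counts over the 6 arrays left out ran from 0 to 1. The study's threshold was met by 310 probe sets with the dimmest probe sets removed, 311 with a floor of 32, 359 with the methods' test, 397 above the bacterial controls and 1250 without both replicate 3 arrays. With 1 array left out it was met by 805 to 1121 (the latter without mutant replicate 3).

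The list calls moved with most settings, and the causes were not tested. Lists past the threshold numbered 0 with a trended prior, array weights, estimated correlation, fry, without both replicate 3 arrays and without the authors' table genes, 1 with a floor of 32, and 0 to 2 with 1 array left out. The placode list lost its call with quantile normalization (-0.25, adjusted p = 0.0624), a median shift (-0.25, 0.0553), an offset of 1 (-0.31, 0.0894) and a floor of 32 (-0.25, 0.125). The placode, neuron and erythroid means were -0.24, 0.15 and -0.16 with a trended prior (adjusted p = 0.0539 for each), with an estimated correlation (0.521, 0.521 and 0.671) and with fry (0.245, 0.0511 and 0.495). With array weights they were -0.27, 0.14 and -0.11 (0.0679, 0.103 and 0.103), without both replicate 3 arrays -0.31, 0.12 and -0.0891, and without the authors' table genes -0.10, 0.13 and -0.14. The neuron list also lost its call with a floor of 32 (0.14, adjusted p = 0.221) and above the bacterial controls (0.11, 0.199). With 1 array left out the means ran from -0.33 to -0.19 for placode markers, 0.13 to 0.16 for neuron markers and -0.25 to -0.11 for erythroid markers. The secreted Wnt inhibitors, not past the threshold in any setting, went to 0.0891 without the authors' table genes, which takes out Dkk4, Wif1 and Apcdd1.

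The replicate number as a block left 0 probe sets and 0 genes past the threshold, 789 at the study's threshold and 0 lists (placode -0.24, adjusted p = 0.121, neuron 0.15, 0.072, erythroid -0.16, 0.072). Deviations of arrays with the same number correlated at 0.038, 0.069 and 0.14 over all probe sets and at 0.14, 0.28 and 0.33 over the 6551 brighter ones, and the block changed no call but those of the 3 lists. Over all probe sets each array correlated best with its own number except wild-type replicate 1, which did so with mutant replicate 2 (0.046), a hint from the data and not from the design.

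For the named genes, 2049 of 2063 values over the alternatives kept their direction and side of the threshold, and 1, Epyc, passed it. Of those that turned sign, Wnt5b went to -0.18 and Hoxa4 to -0.16 when shared-sequence probe sets were removed, which leaves another probe set of the gene, under the bacterial controls in both groups. With 1 array left out Ywhaz ran from -0.0684 to 0.84 and Lef1 from -0.42 to 0.82. Hbb-y, near 0 throughout at its brightest probe set, went to -0.0301 with quantile normalization, -0.0165 with array weights, -0.0509 without wild-type replicate 1, -0.0395 without mutant replicate 3 and -0.035 without both replicate 3 arrays, and lay at -0.27 without shared-sequence probe sets and -0.14 as the mean of its probe sets. With a floor of 32 some dim genes, Kcnd2, Klrb1a, Hoxd11 and Hoxa4 among them, had no difference to give. Signal over background limits the dim genes, since 27 to 29.3% of probe sets lay within the bacterial controls.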

Other observations

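The tests of less epithelium, of whole-gene change, of shared sequence, of strain segments elsewhere and of shared regulation were chosen after the result was seen, as was the use of a standard error in judging the replicate 3 arrays. The tests of other splits of the arrays, of the segment around Trps1 and of leaving out the replicate 3 arrays were set beforehand.

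Several further genes separated the groups without passing over all genes. The class I histocompatibility gene H2-K1 read 244.4 ± 60.8 in wild-type and 132.3 ± 26.4 in mutant pads at its brightest probe set (difference -0.80, limma adjusted p = 0.681), beside H2-D1 at -1.34, while probe sets shared by several class I genes went both ways, from -0.97 for H2-Q5 and H2-K1 to 0.65 for H2-Q6 and H2-Q8. Iigp1, an interferon-inducible GTPase, was measured by 2 probe sets, at 0.83 and 1.57 (limma adjusted p = 0.58 and 0.336 over all probe sets). The corneal proteoglycan keratocan (Kera) read 70.4 ± 32.7 and 131.3 ± 9.31, a difference of 0.84, and its gene stands in one run with Dcn, Lum and Epyc, all of them higher in the mutant and none past the threshold over all genes. On the first principal component the replicate 3 arrays of both groups stood apart, and Lef1, a Wnt-responsive factor of placodes and dermis, read 112 and 96.9 on these and 300.6 to 482.4 on the other 4 arrays.

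With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3 lists past the threshold, the highest of the others 2, and 1 of 10 gave as many as the real one. It gave 723 probe sets at the study's threshold. As many were found in 4 of 10 splits, itself included, and the highest of the others was 941, for wild-type replicates 1 and 3 with mutant replicate 3 against the rest. For probe sets and for genes past an adjusted p under 0.05 the real count was 0 and the highest of the others 0, so 10 of 10 gave as many.

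Placode and follicle markers averaged -0.24 (SE 0.09) in the mutant. Less epithelium in the mutant tissue as the whole cause would lower the epidermis and periderm list by about as much. That list, which shares 0 genes with the placode list, averaged 0.08 (SE 0.15) and differed from it by 0.322 (SE 0.0975). The placode list was picked for its fall on these arrays, so the gap is expected to be too large and does not decide the question. The replicate 3 arrays as the cause are argued against by the value without them, -0.31 (SE 0.02), although with 2 arrays per group the adjusted p was 0.0923 and the call ended. The list's mean per array was 6.86, 6.83 and 6.58 in wild-type and 6.55, 6.52 and 6.48 in mutant replicates 1 to 3. Wild-type replicate 3 thus lay near the mutant arrays, and leaving it out removes the wild-type array with the lowest mean. The mean of -0.10 without Lhx2, Sox21, Dkk4 and the other genes of the authors' deposited table decides nothing about how many genes carry the pattern, since those genes were picked for differing on these same arrays. Less epithelium in the mutant tissue stays open. Fewer or later placodes in the mutant and lower transcript levels within placodes stay open as hypotheses and were not tested.

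Of the probe sets in the authors' deposited table, 24 had another probe set of the same gene with a mean signal of at least 100, and for 8 of them (Ywhaz, Stmn2, Paip1, Pnpt1, Eny2, Luc7l2, Zfp207 and the probe set shared by Hba-a1 and Hba-a2) every such partner differed by under 0.5 of it. Partners outside that table differed by a median of 0.536 of the first over 19 probe sets and by 0.45 over the 17 without a partner in the table, too near the bound of 0.5 to tell whether whole genes or single probe sets differed. The shared globin probe set differed from its partners by -2.65 (limma SE 0.25, adjusted p = 0.0362 over the 8708 probe sets with a bright partner). One partner reached 99.1% of the highest signal of its array, and near the top of the range a fall can be hidden. The other partner lay at 55.4 to 69.3%. It read 11200 ± 1175 in wild-type, as bright as the globin probe set (11200 ± 1449). In mutant pads it read 10920 ± 530 and the globin probe set 1830 ± 459.8. These values argue against a fall of the whole transcript level for the globin probe set, as far as 1 partner can show. Of the other 7, picked for the same disagreement, 0 passed (smallest adjusted p = 0.264, for Pnpt1 at -1.73), so a change of the whole gene's transcript level stays open for those 7. Sequence shared between paralogs at the 8 probe sets themselves is argued against as the common cause. Of the 8, 1, the globin probe set, carries the array maker's mark for it, as do 2981 of the 22626 probe sets tested. Shared sequence at the partners was not tested, and both globin partners carry the mark. Alleles of another strain that alter how a probe binds and alternative transcripts could give such values. Neither was tested, as the labels name no strain and probe sequences were not analysed here.

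Genes at the study's threshold included 23 pairs of neighbours in chromosome order, where 10000 random sets of as many genes had a median of 11 and a 95th percentile of 17, and 0.16% had as many. Random sets take neighbours to vary independently, and the count was not repeated for other splits of the arrays. The excess therefore cannot be told apart from neighbours that vary together between embryos whatever the genotype. Pairs ran the same way in 18 of 23 (permutation p = 0.0058, with directions shuffled over the same genes, since some genes stand in 2 pairs), among them Dcn with Lum, Lum with Kera, Kera with Epyc, Nefl with Nefm, Sox21 with Cldn10 (-1.36 and -0.86) and Lhx2 with Dennd1a (-1.18 and -0.85, the latter -0.56 without mutant replicate 3). The genes 4833420G17Rik, 3110070M22Rik and Tmem267 also stood in one run, at 0.92, 0.72 and 1.05. Shared regulation of neighbouring genes is consistent with those 18 pairs, and segments of another strain elsewhere in the genome are consistent with the 23, so both stay open, for the placode genes Sox21 and Lhx2 as well. A segment around Trps1 itself cannot be told apart from chance, as 8 of the 100 measured genes nearest to it had an unadjusted p under 0.05, where random windows had a median of 5 and a 95th percentile of 9. Zfpm2 is 1 of the 8. The count took each gene's brightest probe set. Eny2, Ccn3 and Ywhaz, at 3, 8 and 26 measured genes from Trps1, are in the window but not among the 8. Their probe sets in the authors' deposited table differed by 0.95, -0.52 and 1.36. Those were picked for differing on these arrays, so they do not decide the question. The genotype as the source of the differences at the neighbouring pairs was not tested apart from the strain.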
